A study of Homo sapiens with 4 samples.

How the data were processed

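Total RNA of 4 samples of MDA-LM2 cells was analysed, 2 transfected with scrambled RNA and 2 with the sRSE decoy, each taken 48 h after transfection. Groups and replicate numbers come from the sample labels. Nothing in the labels says that the replicates were separate cultures, so p-values of single genes measure only the spread between these samples, which may be technical. RNA was labelled with biotin and read on Illumina beadchips, per the labels. The beadchip version is not given in the sources used here.

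The deposited raw values are intensities, the mean bead signal of each of 47323 probes on each array, with no background subtraction and no log transform, per the file headers and the values themselves. Beside each intensity stands the detection p-value that the authors deposited, per the file headers. In sRSE decoy replicate 1, 3 detection cells repeated the signal beside them. They were treated as missing and filled in from the probes nearest in signal. The authors also deposited normalized intensities of the same arrays, processed with lumi per the submitters' processing notes (version not given). In these the 4 arrays share 1 distribution on a linear scale, and each column rises with its array's raw signal. A last deposited table holds 1 value per transcript accession for decoy against scrambled RNA. Its header calls the value a log fold change, with the base unstated. The values fit a log10 ratio of group means of an inverse hyperbolic sine transform of the authors' normalized intensities, a log of values already on a log-like scale, so they are far smaller than a log2 fold change.

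No table given here pairs the probes with genes, and gene names rest on a join by value. For every probe the authors' log10 ratio was recomputed from their normalized intensities with 3 fitted constants, and an accession was linked to a probe where both values agreed within 6e-10 and no other probe or accession did. Of 39747 accessions, 32473 (81.7%) were linked to 1 probe each, 6461 had no probe within the tolerance, 137 had several candidates, and 676 were printed with too few decimals. In 8 tables shifted so that no true link could remain, 108 links were made on average by chance (0.332% of those made). On a simulated table, 5 of 32555 links were wrong, and 98.6% of accessions with 1 probe were linked. Linked accessions were named through the RefSeq gene table of assembly GCF_000001405.40 (GRCh38.p14), used only for names and for which genes neighbour each other. Of them, 16744 have a current symbol, which covers 15358 genes, and 15729 have none. Every gene measured on the arrays is named through this join, while values quoted from the authors' table by accession (those of GAPDH, ACTB and a further accession of APP among them) do not need it.

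Raw intensities were corrected for background by normexp with negative controls inferred from the detection p-values, given an offset of 16, quantile normalized and put on the log2 scale, as limma's neqc does (limma 3.58.1, R 4.3.3). Probes needed a detection p under 0.01 on at least 2 of the 4 arrays, which left 13889 probes, 6804 of them with a gene symbol. A gene was measured by its probe with the highest mean log2 signal, which gave 6480 genes. Of 312 genes with several detected probes, 122 had probes of opposite sign and 15 had probes called in opposite directions. A probe with detection p of 0.01 or more on both arrays of a group was taken as not well above background there. Its fold is given as at least the bright group's mean over the dim group's mean, where each dim array counts as the higher of its own signal and the lowest signal above background. Of the called genes, 189 were of this kind.

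Groups were compared with limma's lmFit and eBayes without covariates, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Errors of log2 fold changes are standard errors of this fit. Before the data were examined, 20 gene lists were fixed, of which 18 had at least 5 measured members and were tested with limma's camera (two-sided, preset correlation 0.01). With the preset correlation, camera's p-values treat genes as the units under that assumed correlation. They do not measure how a list as a whole varies between samples, of which there are 2 per group. Neither of the calls made by camera holds with an estimated correlation. The estimated correlations of both lists were negative, so they do not account for the lost calls. That variant rests on 2 residual degrees of freedom and has little power here, so it cannot decide either call. Also fixed beforehand was the rule for named genes. It takes TARBP2, APP and ZNF395, recalled from the study's later paper, and the called genes with the 12 largest fitted changes in each direction whose arrays separate by group. It adds up to 4 members of each list with the smallest p, and the probes raised in the closing section. Genes named outside this rule are marked as such, and some list members are not reported by name here.

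The fit was tested on simulated data for this comparison, with 200 of 6480 genes changed in 10 draws. It called 92.0% of genes changed by 0.5 on the log2 scale and 100.0% of those changed by 1, 1.5 or 2, with 5.19% of calls among unchanged genes, and with no gene changed it called at most 4. A list moved by 0.3 was called in each of 20 draws, in which no other gene changed. The simulated genes varied independently and needed no normalization. In the data 44.5% of genes passed, and camera compares a list with all other genes, so these rates may not hold there. Alternatives covered the background correction, normalization, offset, use of the authors' normalized intensities, detection filter, choice of probe, variance model, replicate number as a block, each array left out, thresholds and list tests. A further 2 scalings were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the join and the figures.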

Results

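Transcript levels were measured in MDA-LM2 cells, a lung-metastatic derivative of a human breast cancer line, 48 h after transfection with synthetic RNA. The RNA bore a cap and a poly(A) tail and held either tandem copies of an RNA element named sRSE, the decoy, or a scrambled sequence as the control. Each RNA was given to 2 samples, and each sample was hybridised to 1 Illumina expression beadchip, which reads biotin-labelled RNA with 47323 probes. The median raw signal was 77.5 and 76.3 on the scrambled RNA arrays and 83.9 and 81.3 on the sRSE decoy arrays, and the 75th percentiles were 166 and 157 against 208 and 193. A signal above background was detected for 13449 and 13849 probes with scrambled RNA and for 13402 and 13512 with the decoy. Across the 6480 genes tested, log2 signals correlated at r = 0.995 between the scrambled RNA arrays, at r = 0.996 between the decoy arrays, and at r = 0.974 to 0.975 between arrays of different groups (Pearson, across genes, which are not independent replicates). Precision is limited by the number of arrays, 2 per group.

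The comparison of decoy with scrambled RNA asks which transcripts differ when extra copies of the element are present. The decoy is meant to occupy, and so titrate, the cellular factor that binds the element, which these arrays do not measure. The signal of SS18L2, a homologue of the synovial sarcoma protein SS18, was 18.6-fold lower with the decoy (n = 2 arrays per group), the largest fitted change of any named gene. Signals of the interferon regulator IRF1 and the protease inhibitor TFPI2 were lower too, by 2.21-fold and 2.16-fold, as were those of several chemokines and cytokines. Among transcripts measured in both groups, NFE2L1, a transcription factor that drives proteasome genes, rose 2.69-fold, IDE, the insulin-degrading enzyme, rose 2.60-fold, and ZNF395, a zinc finger protein, rose 1.68-fold. In all, 2886 of the 6480 genes (44.5%) passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 1374 higher and 1512 lower with the decoy. Most changes were small. Among the 2696 called genes measured above background in both groups, the median absolute log2 fold change was 0.43, and 39 rose and 7 fell by at least 2-fold. Which direction held more calls depended on the processing. With median scaling in place of quantile normalization the split became 1167 higher and 2237 lower, but it turned to 1470 higher and 1331 lower with cyclic loess, added after seeing the data, and to 1075 higher and 989 lower without a detection filter. Without sRSE decoy replicate 1 or 2 the count fell to 1462 or 1364.

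**Figure D1:**
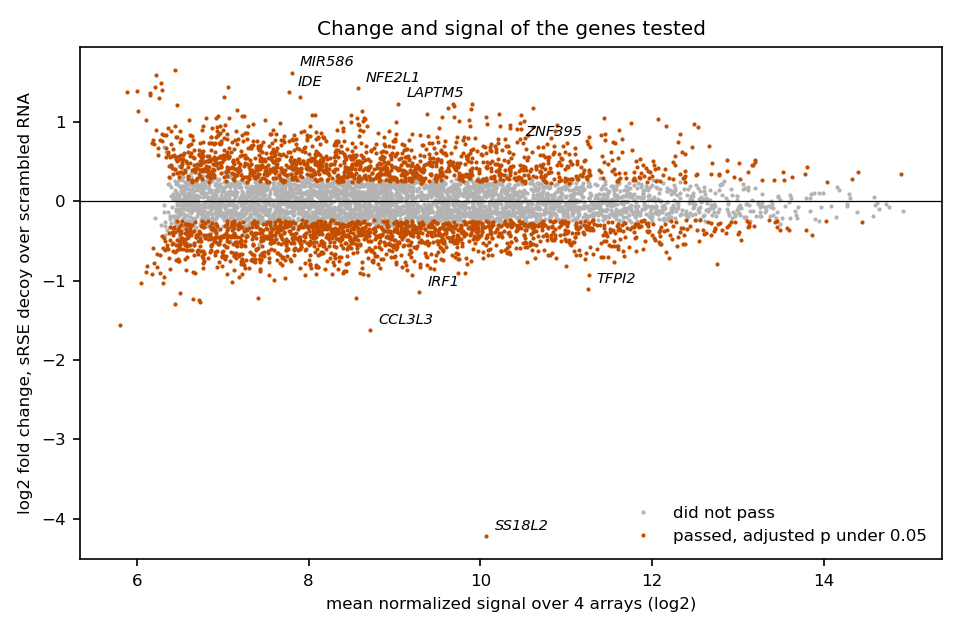
Log2 fold change of each of the 6480 genes tested, sRSE decoy over scrambled RNA (vertical axis), against its mean normalized signal over 4 arrays (horizontal axis, log2); each point is a gene, orange where it passed an adjusted p of 0.05. The 2886 genes that passed lie on both sides of 0 over the whole range of signal, and SS18L2 stands apart at -4.22.

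The arrays of each group lay close together relative to these differences. The median standard deviation of log2 signal was 0.067 within scrambled RNA and 0.065 within the decoy, and the median standard error of a log2 fold change was 0.0903. Both decoy arrays lay above or both below both scrambled arrays in 4891 genes (75.5%), including all 2886 called genes, where chance gives 33.3%. The median log2 fold change of all genes tested was -0.031, and it was -0.12 with median scaling and -0.0073 with cyclic loess.

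Of the 3 genes fixed in advance, ZNF395, a target of the element's binding factor as recalled from the study's later paper, rose by 0.75 ± 0.09 on the log2 scale (SE, n = 2 arrays per group; limma adjusted p = 0.00118). In the authors' deposited table its log10 ratio was 0.0305, at percentile 99.5 of all accessions, where the housekeeping genes GAPDH and ACTB, named outside the fixed rule and chosen after the results were seen, stand at percentiles 98.6 and 97.3. TARBP2, the double-stranded RNA-binding protein recalled as that factor, did not pass. Its brighter probe read -0.21 ± 0.09 on the log2 scale (limma adjusted p = 0.079) and its dimmer probe 0.45 ± 0.16 (limma adjusted p = 0.0475 over all detected probes), so the probes disagree in sign and their mean was 0.12. For APP, the amyloid precursor protein and also recalled as a target, the linked probe was above background on 0 arrays and was not tested. The authors' deposited table lists APP at 0.00965 for the accession of that probe (percentile 92.9) and at 0.0233 for another accession (percentile 98.7).

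By fitted log2 difference, the 12 rises ranked highest were those of GPAT4, MIR586, IDH2, RABGGTA, RFXANK, PPAN, NFE2L1, E2F8, TMEM276, IDE, BMP4 and NOMO3. MIR586 rose by 1.62 ± 0.12, NFE2L1 by 1.43 ± 0.09 and IDE by 1.38 ± 0.11 on the log2 scale (SE, n = 2 per group; limma adjusted p = 4.76e-04, 4.11e-04 and 5.82e-04). MIR586 names the precursor transcript, not the mature microRNA, and whether its probe reads that or another RNA was not tested. The other 9 were not well above background in scrambled RNA, so their rank is not a measured order and their fold is a lower bound, set against the lowest signal that was above background on each array. RFXANK, a subunit of the complex that activates MHC class II promoters, was at least 2.52-fold higher, and GPAT4, an acyltransferase of glycerolipid synthesis, at least 1.77-fold. RABGGTA, a subunit of the enzyme that attaches geranylgeranyl groups to Rab proteins, was at least 1.5-fold higher, mitochondrial isocitrate dehydrogenase IDH2 at least 1.48-fold and the cell cycle repressor E2F8 at least 1.46-fold. PPAN, a ribosome biogenesis factor, was at least 1.40-fold higher, NOMO3 at least 1.30-fold, TMEM276 at least 1.19-fold and the growth factor BMP4 at least 1.09-fold. NOMO3 has near-identical copies that its probe may also read.

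The 12 falls ranked highest by fitted log2 difference were led by SS18L2, which fell by 4.22 ± 0.08 on the log2 scale (SE, n = 2 per group; limma adjusted p = 4.86e-07). The log2 signal of its only detected probe went from 12.18 with scrambled RNA to 7.96 with the decoy. Whether that probe reads SS18L2 or another RNA, such as the transfected scrambled RNA, cannot be told apart here. The chemokine CCL3L3, whose near-identical copies cannot be told from it here, fell by 1.63 ± 0.11, TMEM135 by 1.23 ± 0.17, VKORC1L1, a vitamin K epoxide reductase, by 1.22 ± 0.08, IRF1 by 1.14 ± 0.08 and TFPI2 by 1.11 ± 0.10. The other 6 were not well above background with the decoy and likewise have no measured order. The circadian regulator PER2 was at least 1.83-fold lower, the zinc finger genes ZNF772 and ZNF418 at least 1.79-fold and 1.5-fold, the chemokine CXCL2 at least 1.71-fold, PGBD2 at least 1.49-fold and GFRA3, a receptor of the GDNF family, at least 1.05-fold.

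**Figure D2:**
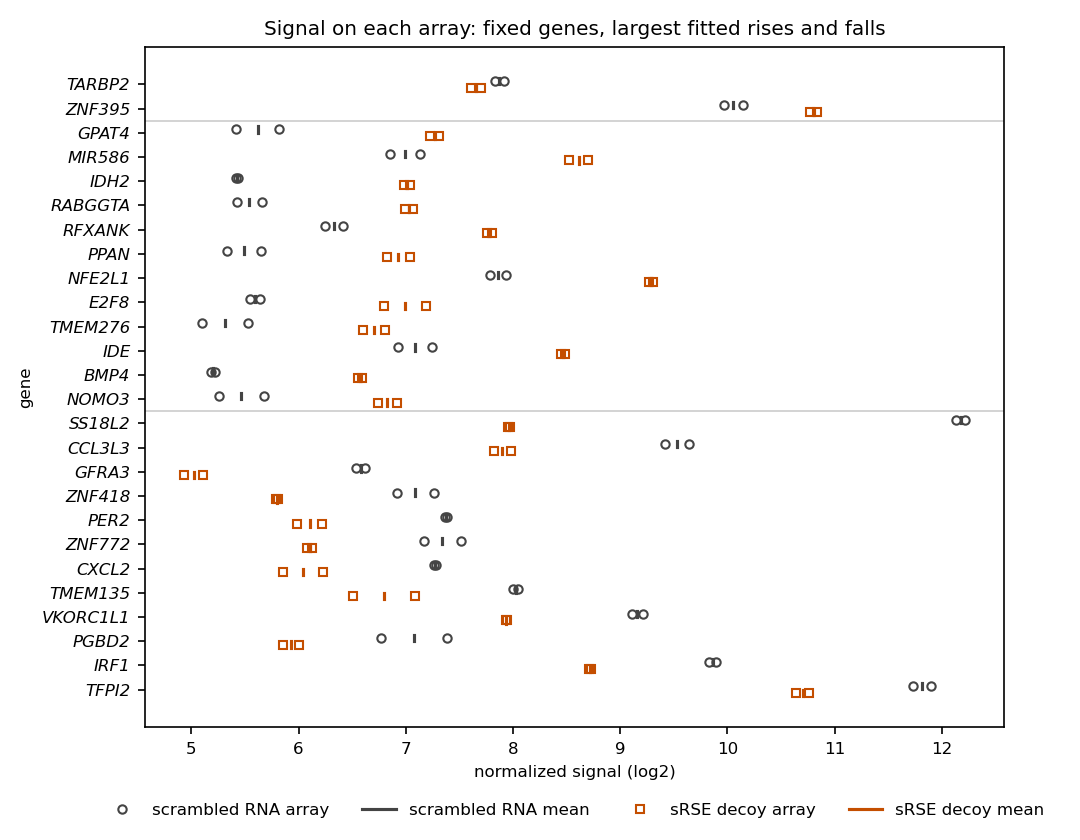
Normalized signal (horizontal axis, log2) of TARBP2 and ZNF395, the 12 rises and 12 falls with the largest fitted differences (vertical axis), with an open circle for each scrambled RNA array, an open square for each sRSE decoy array and a short vertical line for each group's mean. In every gene shown the 2 decoy arrays lie on one side of the 2 scrambled RNA arrays, which was a condition for choosing the rises and falls. The widest gap is that of SS18L2, from 12.18 to 7.96.

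A part of the interferon-stimulated genes fell with the decoy. Of 27 interferon-stimulated genes measured, 12 fell, 1 rose and 14 did not pass, with a median log2 fold change of -0.25, which became -0.16 without sRSE decoy replicate 1 and -0.44 with median scaling. The antiviral factor SAMD9 fell by 0.81 ± 0.08, the membrane protein IFITM1 by 0.77 ± 0.08, the RNA sensor IFIH1 by 0.73 ± 0.09 and IFIT2, which binds viral RNA, by 0.64 ± 0.08. The 1 gene that rose was DTX3L, a ubiquitin ligase, at 0.51 ± 0.10, chosen for naming after its value was seen. The list passed (limma camera, adjusted p = 0.00781), but not with its correlation estimated from these arrays (camera adjusted p = 0.681). That was the highest adjusted p over the alternatives, which began at 7.58e-04. The estimated correlation was -0.035, below the preset 0.01. With 2 residual degrees of freedom that variant has little power, so its outcome decides little. Adjusted over the list alone, 12 fell and 1 rose.

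Most NF-kB targets and cytokines measured fell. Of 17 measured, 11 fell, 3 rose and 3 did not pass, with a median of -0.42. CXCL2 fell as given above, CSF2, the cytokine GM-CSF, fell by 0.93 ± 0.10, interleukin gene IL1A by 0.77 ± 0.08 and mitochondrial superoxide dismutase SOD2 by 0.68 ± 0.08. The 3 that rose were the NF-kB subunit NFKB2, the cytokine LIF and TNFAIP2, named after their values were seen. The list passed (limma camera, adjusted p = 0.0132), but not with an estimated correlation (camera adjusted p = 0.681). It did not pass with median scaling either (camera adjusted p = 0.0511), where its median was -0.48. Over all alternatives of the list test, adjusted p ran from 0.0017 to 0.681. The estimated correlation was -0.037, below the preset 0.01, and that variant has little power with 2 residual degrees of freedom. Adjusted over the list alone, 12 fell and 3 rose. For SOD2 the mean over its 2 detected probes, -0.23, did not pass.

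None of the other 16 lists passed limma camera, whose adjusted p ran from 0.301 to 0.924. The members that changed went both ways in all but 1 of them. Their counts stand beside the 44.5% of all 6480 genes that passed, 1374 higher and 1512 lower. Genes so far unnamed by the fixed rule that are given below to complete a count of 5 or fewer were chosen after their values were seen.

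The lists of cell cycle genes did not pass (limma camera, adjusted p = 0.301 for both), and their medians of 0.13 for G2/M and 0.097 for G1/S became -0.19 and -0.13 with median scaling. Of 31 genes of G2/M and mitosis, 12 rose, 3 fell and 16 did not pass (13 rose and 4 fell adjusted over the list alone). The spindle factor TPX2 rose by 0.81 ± 0.09 and the proliferation marker MKI67 by 0.76 ± 0.08, while ECT2, needed for cytokinesis, fell by 0.93 ± 0.10, CKAP2 by 0.77 ± 0.08, and PLK1 was the third to fall. Of 24 genes of G1/S and DNA replication, 7 rose, 3 fell and 14 did not pass (7 and 3 over the list alone). RFC2, a subunit of the clamp loader, rose by 1.00 ± 0.10, the helicase subunit MCM5 by 0.84 ± 0.08 and thymidine kinase TK1 by 0.67 ± 0.08, and MCM7 was at least 1.12-fold higher. CDT1, MCM6 and RPA2 fell.

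Some lysosomal genes rose, while the list's median was 0.0038. It became -0.041 without scrambled RNA replicate 2 and -0.18 with median scaling. Of 23 measured, 8 rose, 2 fell and 13 did not pass (8 and 2 adjusted over the list alone; limma camera, adjusted p = 0.487). The protease gene CTSD rose by 1.01 ± 0.10, the sialidase NEU1 by 0.99 ± 0.08, CTSA, which protects NEU1, by 0.95 ± 0.10 and the proton pump subunit ATP6V0D1 by 0.84 ± 0.10. The pump subunit ATP6V1A and the protease CTSL fell. Of 21 hypoxia and glycolysis genes, 6 rose and 5 fell (the same counts over the list alone; adjusted p = 0.657). The 4 with the smallest p rose, GPI by 1.01 ± 0.10, ALDOA by 0.76 ± 0.10, PKM by 0.70 ± 0.08 and PFKL by 0.51 ± 0.08. They encode glycolytic enzymes, but so does ALDOC, which fell, as did PFKFB4, ADM, ANKRD37 and VEGFA. Glycolytic enzymes were not tested as a set of their own. The list's median was -0.028 and its mean 0.089, with an upward test. With 1 array left out the median ran from -0.0062 to 0.027, and it was -0.27 with median scaling.

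Genes of mRNA decay moved in both directions. Of 33 genes of mRNA decay, 7 rose and 6 fell (7 and 6 over the list alone; limma camera, adjusted p = 0.697). LSM4 rose by 0.99 ± 0.08 and the exosome subunit EXOSC4 by 0.79 ± 0.13, while the exonuclease XRN1 fell by 0.58 ± 0.08 and UPF2, a factor of nonsense-mediated decay, by 0.55 ± 0.08. Of 9 genes of the small RNA silencing machinery, which holds TARBP2, 0 rose and 2 fell (0 and 1 over the list alone; adjusted p = 0.866). The RNA helicase DDX5 fell by 0.40 ± 0.10 and PRKRA, a partner of Dicer, by 0.29 ± 0.10, and the RNA editing enzyme ADAR read -0.15 ± 0.08, which did not pass. ADAR passed in opposite directions elsewhere, at -0.49 with median scaling, -0.33 with scaling over probes detected on all 4 arrays, and 0.26 as the mean of its probes. DDX5 did not pass without sRSE decoy replicate 1 (-0.34), scrambled RNA replicate 2 (-0.31) or sRSE decoy replicate 2 (-0.46), nor PRKRA without any 1 of the arrays (-0.19 to -0.38) or with cyclic loess (-0.26), and neither passed without a detection filter. This list's median was 0.068, its mean -0.044 and its test downward.

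Chaperone and stress genes were split. Of 14 heat shock chaperones, 6 rose and 3 fell (6 and 3 over the list alone; limma camera, adjusted p = 0.487). The HSP90 co-chaperones AHSA1 and STIP1 rose by 0.89 ± 0.09 and 0.62 ± 0.08, whereas HSPA1A and HSPA1B, near-identical genes that a probe may not tell apart, fell by 0.55 ± 0.10 and 0.46 ± 0.08. DNAJA1 also fell. Of 21 genes of the integrated stress and unfolded protein response, 5 rose and 7 fell (7 and 7 over the list alone; adjusted p = 0.866). The transcription factor ATF4 rose by 0.74 ± 0.10 and the disulphide isomerase PDIA4 by 0.54 ± 0.09, while ATF5 fell by 0.73 ± 0.09 and the chaperone DNAJB9 by 0.45 ± 0.08. PDIA6, VLDLR and CALR also rose. Of 9 p53 targets, 2 rose and 2 fell (2 and 2 over the list alone; adjusted p = 0.924). The death receptor TNFRSF10B fell by 0.84 ± 0.10 and TRIAP1 by 0.53 ± 0.09, TP53I3 rose by 0.43 ± 0.10, and DDB2, a DNA damage sensor, was at least 1.17-fold higher. The p53 median was 0.0078, its mean -0.022 and its test upward. TP53I3 did not pass without sRSE decoy replicate 2 (0.36).

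Among lung metastasis signature genes, 1 of 11 rose and 4 fell (1 and 5 over the list alone; limma camera, adjusted p = 0.487). The matrix protein EFEMP1 rose by 0.70 ± 0.09. CXCL1 fell by 0.93 ± 0.18, KYNU by 0.83 ± 0.11, the NF-kB inhibitor TNFAIP3 by 0.45 ± 0.09, and the actin bundler FSCN1 was the fourth, with CXCL1 and TNFAIP3 also counted among the NF-kB genes. Without sRSE decoy replicate 2 neither CXCL1 (-0.70) nor TNFAIP3 (-0.45) passed, and TNFAIP3 did not without sRSE decoy replicate 1 (-0.44). Of 20 mesenchymal and extracellular matrix genes, 5 rose and 4 fell (5 and 4 over the list alone; adjusted p = 0.657). TIMP3, a metalloproteinase inhibitor, rose by 0.94 ± 0.08 and the urokinase receptor PLAUR by 0.77 ± 0.10, and COL6A1 and COL4A2 were among the others that rose. Smooth muscle actin ACTA2 fell by 0.93 ± 0.11 and SERPINE2 by 0.71 ± 0.08, with ZEB2 and LAMC1. Of 7 epithelial markers, 4 rose and 2 fell (4 and 2 over the list alone; adjusted p = 0.657), with CLDN7 up by 0.80 ± 0.09, KRT19 up by 0.61 ± 0.10 (0.26 and not passing with median scaling), KRT8 and KRT7 also up, MUC1 down at -0.58 ± 0.08 and KRT17 at least 1.25-fold lower.

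Of 17 immediate early genes, 3 rose and 5 fell (3 and 5 adjusted over the list alone; limma camera, adjusted p = 0.632). FOSL1, a subunit of the AP-1 transcription factor, rose by 1.02 ± 0.09 and CCN1 by 0.35 ± 0.08, a value that became -0.066 with median scaling, and IER5 rose too. CCN1 did not pass without sRSE decoy replicate 1 (0.36) or 2 (0.34), or with scaling over probes detected on all 4 arrays (0.14). The signalling inhibitor SPRY2 fell by 0.70 ± 0.08 and the repressor BHLHE40 by 0.41 ± 0.08, with DUSP1, ZFP36 and JUN. Of 15 cholesterol biosynthesis genes, 3 rose and 1 fell (3 and 1 over the list alone; adjusted p = 0.757). EBP rose by 0.61 ± 0.08 and PMVK by 0.34 ± 0.08, MVD was at least 1.10-fold higher, and SC5D fell by 0.37 ± 0.10. Without sRSE decoy replicate 1 or 2, MVD, PMVK (0.35 and 0.32) and SC5D (-0.46 and -0.29) did not pass, nor did SC5D without scrambled RNA replicate 1 (-0.28) or without a detection filter.

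Of 55 genes of oxidative phosphorylation, 8 rose and 14 fell (7 and 14 adjusted over the list alone; limma camera, adjusted p = 0.657). NDUFA11 rose by 0.62 ± 0.11 and UQCRC1 by 0.61 ± 0.08, while SDHD fell by 0.55 ± 0.09 and NDUFC1 by 0.53 ± 0.08. NDUFA11 did not pass without sRSE decoy replicate 2 (0.60). Of 50 cytosolic ribosomal proteins, 9 rose and 11 fell (9 and 11 over the list alone; adjusted p = 0.657). RPS2 rose by 0.97 ± 0.08, RPL4 by 0.84 ± 0.09 and RPL13A by 0.69 ± 0.09, while RPL26 fell by 0.88 ± 0.09. With median scaling both lists passed as lower, with medians of -0.36 and -0.54 in place of -0.067 and -0.081.

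Few markers of other cell types were measured. A marker counts as measured only if a detected probe was linked to it by the join, so those not measured may still be expressed. Of 22 blood cell markers, 4 were measured, too few for a list test. LAPTM5, a lysosomal membrane protein of blood cells, rose by 1.23 ± 0.08 and CD74 by 0.45 ± 0.09, CD14 fell by 0.33 ± 0.11, and CSF1R read -0.12 ± 0.08 (limma; 2 rose and 1 fell adjusted over the list alone). Of 18 fibroblast and endothelial markers, 1 was measured, the endothelial adhesion molecule PECAM1, which rose by 0.78 ± 0.14 (also adjusted over the list alone). Without sRSE decoy replicate 2, PECAM1 (0.73), CD74 (0.37) and CD14 (-0.47) did not pass, nor did CD14 without sRSE decoy replicate 1 (-0.20) or scrambled RNA replicate 2 (-0.25), with median scaling over all probes (-0.27) or those detected on all 4 arrays (-0.24), with cyclic loess (-0.30), or without a detection filter.

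**Figure D3:**
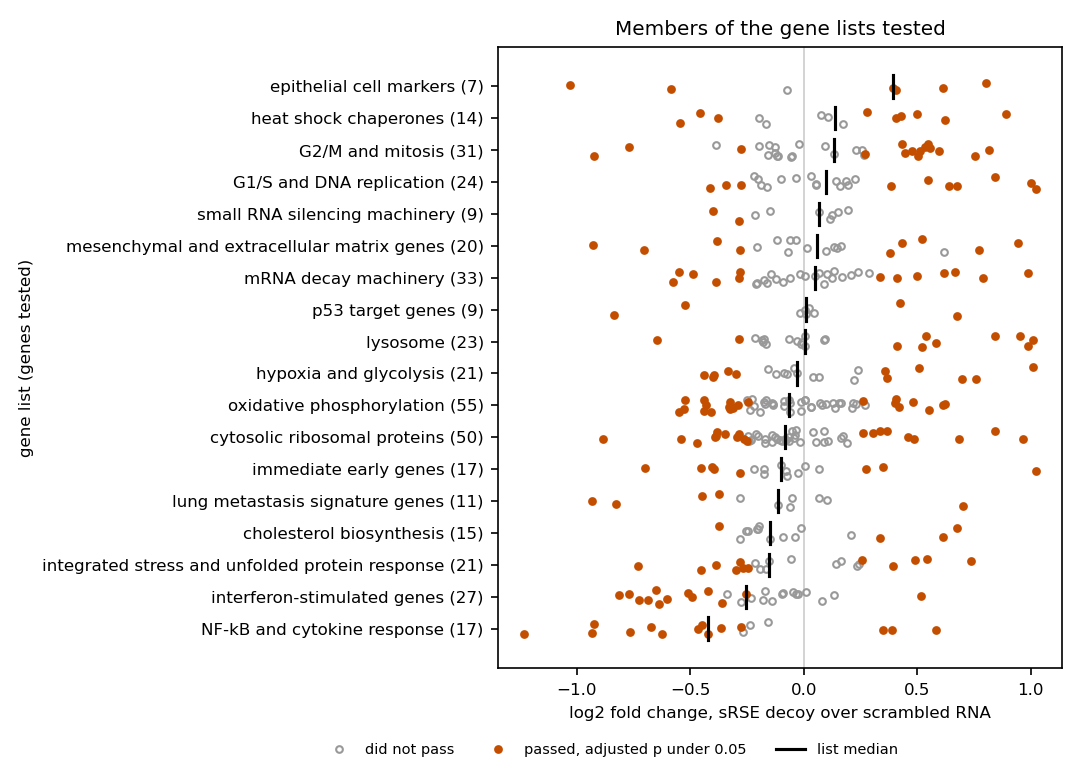
Log2 fold change, sRSE decoy over scrambled RNA (horizontal axis), of the measured members of the 18 lists tested (vertical axis, with the number of genes tested), where each point is a gene, filled where it passed an adjusted p of 0.05, and a black line is the list's median. The NF-kB and interferon lists have the lowest medians, -0.42 and -0.25, and every list has members on both sides of 0.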

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

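Probes that no comparison by gene covers carried signal too. Of 7085 detected probes without a gene symbol, 3104 (43.8%) passed an adjusted p of 0.05 when each detected probe was tested on its own (limma), 1531 higher and 1573 lower with the decoy. Among those detected on all 4 arrays, the largest fall was that of probe ILMN_3307782, at -3.11 ± 0.09 on the log2 scale (limma adjusted p = 8.52e-06), an 8.65-fold lower signal on 2 of 2 decoy arrays. The largest rise among those was that of probe ILMN_3224758, at 2.27 ± 0.09 (limma adjusted p = 3.28e-05), a 4.82-fold higher signal on 2 of 2 decoy arrays. ILMN_3307782 was linked to no transcript and ILMN_3224758 to a transcript without a current symbol, so neither has a gene name here. Whether either probe reads a transfected RNA was not tested. Probes not well above background in 1 group have only a lower bound for their change and are not ranked against these.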

How the results depend on the processing

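Cyclic loess and median scaling over the probes detected on all 4 arrays were chosen after seeing the data. Under the alternatives that keep all 4 arrays and test 1 value per gene, the count of called genes stayed between 2064 and 3404, and with other thresholds it was 3519 (adjusted p under 0.1) or 3450 (unadjusted p under 0.05). Of the 2886 calls, 2705 remained with cyclic loess and 2354 with median scaling, where 34.3% of calls were higher against 47.6%. The majority turned to higher with cyclic loess (1470 higher, 1331 lower) and without a detection filter (1075 higher, 989 lower, with more genes tested). With each detected probe tested on its own, 6018 passed, 2973 higher and 3045 lower, as more units are tested. With 1 array left out, the lone array being assumed to vary like the other group, 1364 to 2489 genes passed, 668 to 1216 higher and 696 to 1276 lower, and 1333 to 2264 of the calls remained. The replicate number as a block gave 2828 calls, and replicates 1 deviated from their group means with r = -0.011 between groups (across genes), so the numbers are not treated as pairs. The block changed neither list call. The authors' final table has 1 column for the comparison and none for the samples, so it was not run as an alternative. Both list calls held with each array left out. Camera with an estimated correlation called 0 lists (0 at an unadjusted p under 0.05), and fry, which asks only whether a list's genes move one way, called 6. Fry added G2/M (fry adjusted p = 0.00813), heat shock chaperones (0.00912) and G1/S (0.0193) as higher. It also added the lung metastasis signature genes as lower (fry adjusted p = 0.0227). Median scaling over probes detected on all 4 arrays called 4, adding oxidative phosphorylation and ribosomal proteins. Reversed values were CCN1 at -0.066 with median scaling, and TARBP2 at 0.12 and ADAR at 0.26 with the mean of all detected probes. Over all settings, values of named genes, reversed ones included, lost the call 38 times, gained it 3 times and stayed on their side of the threshold 1455 times. The cause was not tested except where stated. Signal over background limits the fold of called genes not well above background in 1 group, of which 189 have a bound of at least 1-fold.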

Other observations

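The tests of symbol families, of the distance between links, of array splits, of cyclic loess, of neighbouring genes and of a uniform interferon fall were chosen after the results were seen. Genes that share the first 3 letters of their symbol were grouped into 77 families of at least 12 tested genes, and none passed limma camera after adjustment over the families, while 7 had an unadjusted p under 0.05. The family nearest to the threshold was that of the ZNF zinc finger genes, with 12 higher, 62 lower and a median log2 fold change of -0.15 over 173 genes (adjusted p = 0.0678; adjusted p = 0.908 with an estimated correlation). Next came the KLH genes, which hold the kelch-like adaptors of ubiquitin ligases, with 1 higher, 8 lower and a median of -0.33 over 15 genes (adjusted p = 0.188). The CDK family followed with 7 higher and 1 lower of 20 (adjusted p = 0.273) and the SNO family with 3 higher and 10 lower of 31 (adjusted p = 0.388). The KIF kinesin motors had 8 higher and 3 lower of 19, and the HNR family of RNA-binding proteins 10 higher and 3 lower of 21 (adjusted p = 0.415 for both). Last of the 7 was the IFI family, which shares members with the interferon list. It had 2 higher, 6 lower and a median of -0.32 over 12 genes (limma camera, adjusted p = 0.478).

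SS18L2 signal was 18.6-fold lower with the decoy, far beyond the next largest fall measured in both groups for a named gene, CCL3L3 at 3.09-fold. A chance link of the gene's name to a wrong probe was argued against by the distance of 0.0444 on the log10 scale from the authors' deposited value to the next nearest probe, where links were made within 6e-10. Only 1 detected probe is linked to SS18L2, so it cannot be told apart whether the SS18L2 transcript fell or whether the probe reads another RNA, such as the transfected scrambled RNA, which has a poly(A) tail and may be labelled with the cell's own RNA. An effect of the decoy on SS18L2 stays open as a hypothesis.

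Of 6480 genes tested, 2886 (44.5%) passed. Cyclic loess left 2801 calls, 2705 of them shared. The 2886 calls were made after quantile normalization, which already gives the arrays 1 distribution. Cyclic loess evens out much the same differences, so it cannot tell whether an intensity-dependent difference between arrays contributed. Of the 3 splits of the 4 arrays, 1 gave as many calls, the real one, and the highest other gave 0 (9 at an unadjusted p under 0.05; limma), but 3 splits are too few for a share under 0.05. Changes of neighbouring tested genes correlated weakly (Pearson r = 0.0701, Spearman rho = 0.061 over 6381 pairs, across genes, which are not independent). Pairs in which both genes are ZNF genes were left out, and with them kept r was 0.0723. The one-sided permutation p was 1e-04, the smallest that 10000 permutations can give. A small part of the changes may thus be shared between neighbouring genes. Near-identical neighbours other than ZNF genes, which a probe may not tell apart, were not left out. Differences in RNA handling, culture or dose of transfected RNA between the groups were not tested and stay open beside an effect of the decoy.

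Interferon-stimulated genes passed as a list with a median of -0.25 (limma camera, adjusted p = 0.00781), but not with an estimated correlation (camera adjusted p = 0.681). That variant, with 2 residual degrees of freedom, had little power to call any list. The 95% intervals of 16 of 27 members excluded the median, 7 above it and 9 below, where chance gives 1.35 if members vary independently. In every setting 10 to 17 were outside, against a 95th percentile of chance of at most 4. This argues against a uniform fall only relative to the spread between these arrays, which may be technical. Such scatter is not particular to the list, since 3450 of all 6480 genes had an unadjusted p under 0.05 (limma). The count of members on both sides of the median replaced an earlier one of the members above it alone. That earlier count ran from 1 to 8 around its bound of 6.75 and left the question open. A different response to each transfected RNA may contribute as well as titration of the binding factor. These could not be told apart here, and no untransfected sample was analysed.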
